A study of Staphylococcus aureus with 12 samples.

How the data were processed

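RNA was sequenced from Staphylococcus aureus UAMS-1, a strain first isolated from a patient with osteomyelitis, grown in aerobic tryptic soy broth. Per the labels, cultures were started at an optical density of 0.025 and grown for 2 h at 37 °C and 250 rpm. They were then given sorghum lignin made soluble with alkali, at 5 mg/ml in MOPS buffer (50 mM, pH 7.2), or the buffer alone. Cells were harvested 20 min and 2 h later. The 12 libraries form 4 groups of 3 replicates. The labels do not say whether the replicates of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Per the labels' protocols, genomic DNA was digested, ribosomal RNA was depleted, and libraries with an insert of about 200 bp were made with a kit that does not keep the strand. Reads from a gene and from a transcript antisense to it can therefore not be told apart.

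The authors deposited 2 tables, one per time point, each with the same 3089 features. Per the file headers, the reads were those left over as unmapped from an earlier step, whose target is not given in the sources used here, and features were placed on a reference named for strain MRSA252. The aligner and its settings are not given in the sources used here. Per the file headers, each library has total gene reads and unique gene reads, which are whole-number counts, and RPKM, which are reads scaled for feature length and for mapped reads. The deposited normalized expression values are RPKM after a step that gave all 6 libraries of a table the same set of sorted values, as quantile normalization does (largest difference between sorted values 0). The authors' deposited tables also give fold changes between group means of these normalized values.

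The total gene reads were used as the main counts. They summed to 8134362 to 17001363 reads per library, which was 88.1 to 89.8% of the mapped reads implied by the RPKM values. Reads matching a single place made up 93.3 to 96.0% of the total. Of the 3089 features, 803 carried a gene symbol, 1933 carried only a locus tag beginning with SAR, 277 were numbered with the prefix SARs, 60 were tRNA and 16 were rRNA. The files do not pair the locus tags with names, and the reference gene table at hand covers another strain, so locus tags were left unnamed. The rRNA features held 0 reads, and tRNA features held 5 to 134 reads per library; both classes were left out of the tests. In all, 987 features overlapped another by at least 1 base, and 288 held no reads in any library. Positions are given as in the files, on the MRSA252 reference, counted from 1.

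Counts were tested with edgeR 4.0.16 in R 4.3.3: features passing filterByExpr, TMM scaling, and the quasi-likelihood F test with robust estimation. Tests were two-sided and were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. Lignin was compared with MOPS within each time point on its own 6 libraries. The difference between the lignin effects at 2 h and 20 min was tested in all 12 libraries, and the change with time in MOPS was tested in the 6 MOPS libraries. CPM values are counts scaled to a common library size after TMM scaling within the libraries of a comparison. Standard errors (SE) were obtained from the fold change and its F statistic. Lists of genes were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01. The 44 lists, the comparisons, the tests and the rule for naming genes were fixed before the data were examined. At each time 39 lists had the required 4 tested members. Many fixed members were not found under a symbol: 6 of 15 were found for fermentation, 18 of 41 for iron and 9 of 22 for agr and toxins. Counts below are therefore of measured members and not of whole pathways. Some lists also joined related genes: nrdD and nrdG with nitrate respiration, pdhA to pdhD with glycolysis, aroA, aroB, aroC and aroE with tryptophan, and mprF with D-alanylation.

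Named genes were, per lignin comparison, (a) the 8 with the largest rise and the 8 with the largest fall that passed the test, had a symbol and a mean of at least 10 CPM, showed no overlap between the libraries of the 2 groups, and shared their first 3 letters with at most 1 other gene named in that direction. They were also (b) up to 4 members, those with the smallest p, of each list described, and (c) the regulators vraS, vraR, walK, walR, graS, graR, saeR, saeS, agrA, sigB and sarA, of which walK and walR stand in the files as yycG and yycF while vraR, graS and graR do not stand there under these names. For the difference between times and for time in MOPS, 5 genes were named in each direction under rule (a). Any other feature named was chosen after its values were seen.

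On counts simulated from the means, library sizes and dispersions of the real libraries, with 200 changed genes, the 20 min fit of 2597 genes called 13.4% of the genes changed 2-fold and 87.7% of those changed 4-fold. The 2 h fit of 2567 genes called 49.2% and 92.2%. The fit for the difference between times, on 2626 genes, called 6.0% and 60.6%, and the MOPS time fit, on 2585 genes, called 31.3% and 89.4%. Alternatives were RLE scaling, total counts without TMM, DESeq2 1.42.0, no filter or a 10 CPM filter, an absolute log2 fold change of at least 1, an adjusted p under 0.01, rRNA and tRNA kept, the replicate number as a block, all 12 libraries in one fit, and each library left out. Camera with an estimated correlation and fry were alternatives for the lists. Unique gene reads, the authors' normalized RPKM on a log2(value + 1) scale in limma with a mean of at least 1, the removal of SARs features, and the overlap without lignin 20 min replicate 1 were added after seeing the data. Figures were drawn with matplotlib 3.10.9.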

Results

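The design compares gene expression of S. aureus with soluble lignin and with buffer alone, 20 min and 2 h after the addition, in a series that per its title concerns the cell envelope. Total gene reads ranged from 13216564 to 15074806 in the 3 MOPS libraries of 20 min, from 14602228 to 17001363 in the 3 lignin libraries of 20 min, from 8134362 to 12144767 in the 3 of MOPS at 2 h and from 12880192 to 15202973 in the 3 of lignin at 2 h. No replicate pair agreed within sampling noise, since the lowest chi-square per degree of freedom was 9.67, between replicates 2 and 3 of MOPS at 2 h. Values below are means ± SD in CPM over 3 libraries per group unless stated otherwise.

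After 20 min of lignin, 7 of 7 urease, 8 of 18 iron uptake and 4 of 9 tryptophan list genes were higher than in MOPS. Lower were 7 of 12 of the TCA cycle and 3 of 5 of a list that joins teichoic acid D-alanylation genes and mprF. As lists, none of these held with an estimated correlation. ureC, the large urease subunit (2442301 to 2444016), stood at 525 ± 92.1 CPM with lignin and 156 ± 31.9 in MOPS. The collagen adhesin gene cna fell to 309 ± 154 from 1854 ± 266 CPM, and citZ, encoding citrate synthase, fell to 379 ± 91.0 from 1377 ± 228 CPM. In all, 510 of 2605 features changed, 237 of them higher and 273 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 157 carried a symbol, 336 a locus tag only, and 17 were SARs features.

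**Figure D1:**
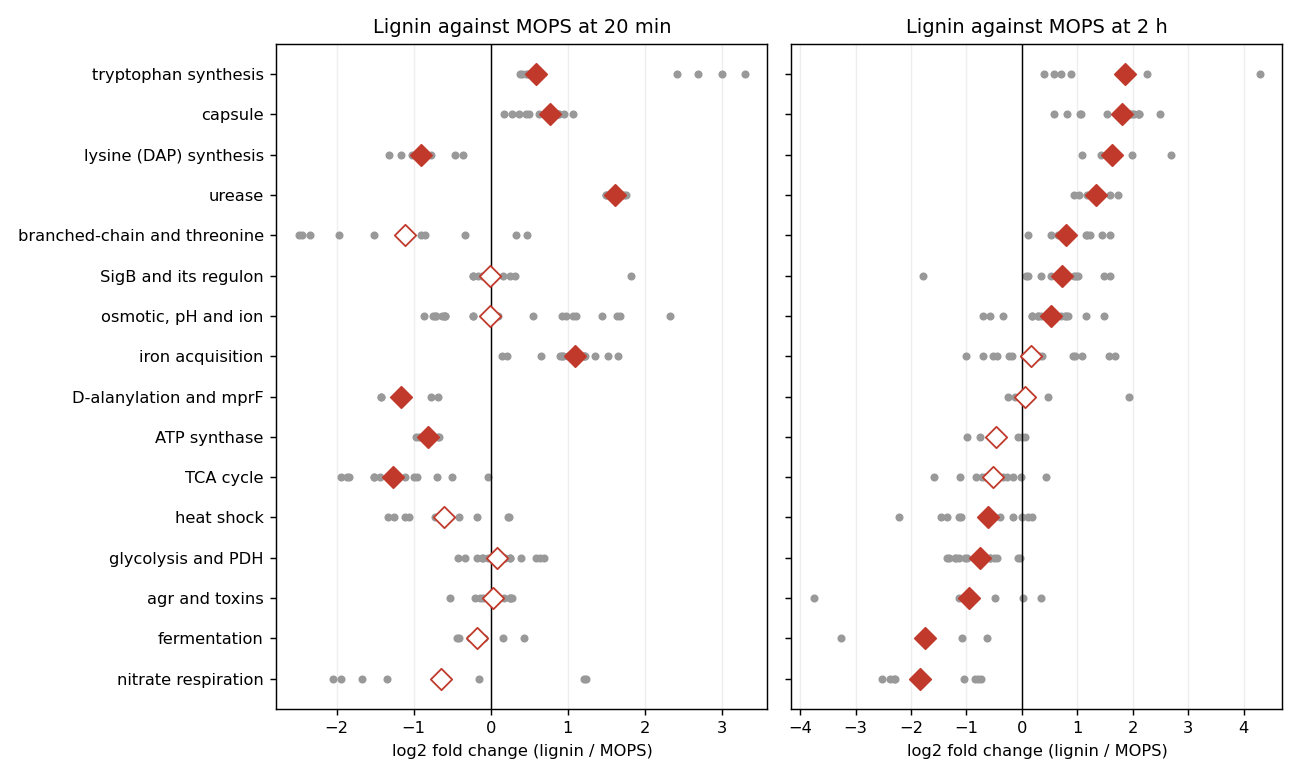
Log2 fold changes of lignin against MOPS at 20 min (left) and 2 h (right) for the gene lists that moved at either time; grey points are single genes and diamonds are list medians, filled where camera with the preset correlation called the list. All 7 urease genes rose at both times, while 4 of 6 lysine genes fell at 20 min and 6 of 6 rose at 2 h; no filled list was called with an estimated correlation.

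Under naming rule (a), with its minimum of 10 CPM and its limit per 3-letter stem, the largest rises at 20 min were in trpC and trpF of tryptophan synthesis, with log2 fold changes of 3.30 (SE 0.72) and 3.00 (SE 0.66). Under that rule sasF, for a surface protein, came next at 2.88 (SE 0.46), then acpD at 2.79 (SE 0.60) and kdpA, for potassium uptake, at 2.33 (SE 0.57). The surface protein gene sdrC rose by 2.16 (SE 0.25), and the riboflavin synthesis genes ribE and ribA rose by 2.04 (SE 0.53) and 2.00 (SE 0.56). The largest falls under it were in scrA, for sucrose uptake, at -2.90 (SE 0.50), gntP, for gluconate uptake, at -2.77 (SE 0.60), and cna at -2.59 (SE 0.38). ilvC, ilvH and leuA of branched-chain amino acid synthesis followed at -2.49, -2.45 and -2.34, with malA at -2.42 and scrR, named for a sucrose operon regulator, at -2.29. The edgeR adjusted p of these 16 genes lay between 0.00939 (sdrC) and 0.0493 (ribA).

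Of the 39 lists tested at 20 min, camera with the preset correlation called 4 up and 4 down, with adjusted p from 3.48e-07 (urease) to 0.0175 (lysine). None of the 8 calls held with an estimated correlation: adjusted p = 0.655 for iron acquisition and tryptophan and adjusted p = 0.713 for the other 6, all with an estimated correlation. Each of the 10 splits of the 6 libraries gave at least 8 lists, and up to 19. Urease rose in 7 of 7 genes, iron acquisition in 8 of 18, capsule in 5 of 16 and tryptophan synthesis in 4 of 9. The TCA cycle fell in 7 of 12, ATP synthase in 3 of 9, the GraRS and D-alanylation list in 3 of 5 and lysine and diaminopimelate synthesis in 4 of 6; no other member of these 8 lists passed the test. Adjusted over the list alone, the counts were 7 for urease, 10 for iron, 8 for capsule, 4 for tryptophan, 10 for the TCA cycle, 8 for ATP synthase, 5 for D-alanylation and 4 for lysine.

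Among the members, ureB rose by 1.71 (SE 0.21, edgeR adjusted p = 0.0101) and ureC by 1.75 (SE 0.23, edgeR adjusted p = 0.0114). fhuB, for ferric hydroxamate uptake, reached 152 ± 15.5 against 76.0 ± 5.89 CPM, and sstA, of an iron transporter, reached 81.0 ± 7.80 against 38.0 ± 6.06 CPM. The capsule genes capN and capL rose by 0.88 and 0.86, and trpB rose by 2.69. citC, for isocitrate dehydrogenase, fell by 1.95 and sucC, for succinyl-CoA synthetase, by 1.43 on the log2 scale. The ATP synthase genes atpI and atpE fell by 0.93 and 0.97. dltC and dltD, which place D-alanine on teichoic acids, both fell by 1.43, and the lysine pathway genes dapA and dapD fell by 1.02 and 1.32 on the log2 scale.

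None of the 8 regulators measured passed the test at 20 min with edgeR. The cell wall stress sensor gene vraS came nearest, at 161 ± 29.7 CPM with lignin and 339 ± 164 in MOPS (edgeR adjusted p = 0.067), and passed with DESeq2 or with all 12 libraries in one fit. The sensor gene yycG (walK) had a log2 fold change of -0.50 and its regulator yycF (walR) of -0.52, with adjusted p = 0.18 and adjusted p = 0.1 in edgeR, and both passed without lignin replicate 1. With the replicate number as a block in edgeR, 1 of vraS, yycG and yycF also passed. saeR and saeS stood at -0.46 and -0.50, sarA at -0.17, agrA at 0.25 and sigB at 0.03.

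Lignin replicate 1 of 20 min stood apart: over genes, its log2 CPM correlated with replicates 2 and 3 at 0.905 and 0.914, while those correlated with each other at 0.992. It correlated more highly, at 0.949, 0.940 and 0.942, with MOPS 20 min replicates 1, 2 and 3. Its correlations with lignin 2 h replicates 1, 2 and 3 were 0.9324, 0.9465 and 0.9434. Without it, 1050 features passed (529 higher, 521 lower), and the tryptophan, D-alanylation and lysine lists were no longer called while purine synthesis was, down (camera adjusted p = 0.000375, and adjusted p = 0.932 with an estimated correlation). The tryptophan list then had 4 of 9 genes risen, 1 fallen and a median of 0.43, against 0.59 with it. The D-alanylation list had 5 of 5 genes fallen and a median of -1.27, against -1.17 with it, and the lysine list 4 of 6 fallen and a median of -0.99, against -0.90. Among lists still called, ATP synthase had 9 of 9 and the TCA cycle 10 of 12 genes fallen. Capsule had 9 of 16, iron acquisition 13 of 18 and urease 7 of 7 genes risen. Without lignin replicate 2 a single feature passed, without lignin replicate 3 it was 52, and without MOPS replicates 1, 2 and 3 it was 132, 76 and 318. No named call at 20 min held under every removal. The stretch of 68 features from sak to int (2128315 to 2168433) moved with this split: its median log2 change from the mean of MOPS was 4.73 and 4.61 in replicates 2 and 3 and -0.09 in replicate 1. With all libraries kept, 21 of its 56 tested features were called at 20 min, all of them higher. Fitted together with the 2 h libraries, 816 features passed, and with DESeq2 795 passed.

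**Figure D2:**
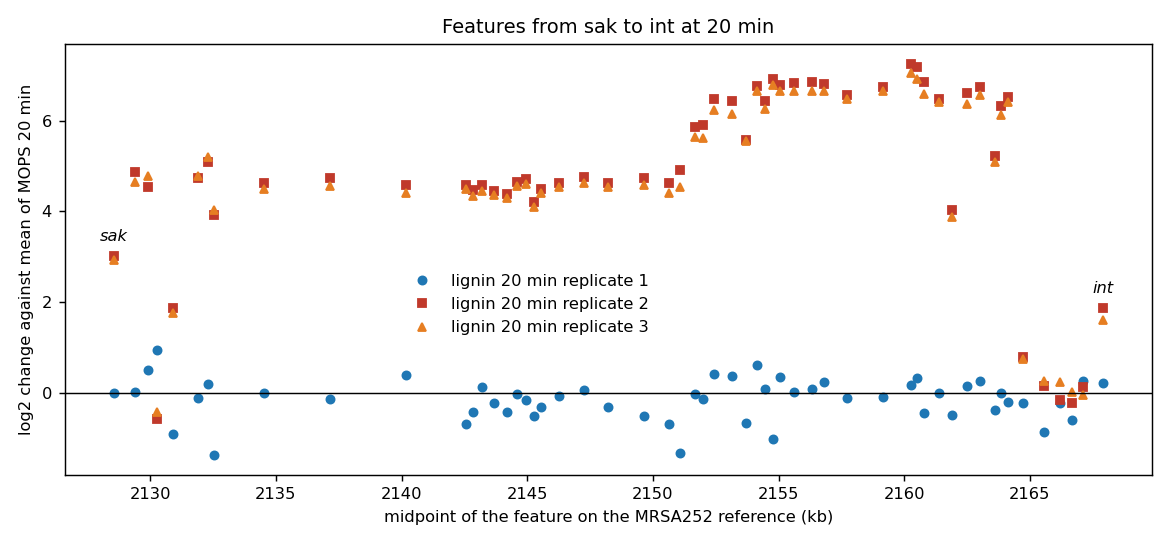
Log2 change of each tested feature from sak to int against the mean of the 3 MOPS libraries at 20 min, by position on the MRSA252 reference in kb; each point is a feature in 1 lignin library. Replicates 2 and 3 lie together far above the line of no change over most of the stretch, and replicate 1 lies near that line.

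**Figure D3:**
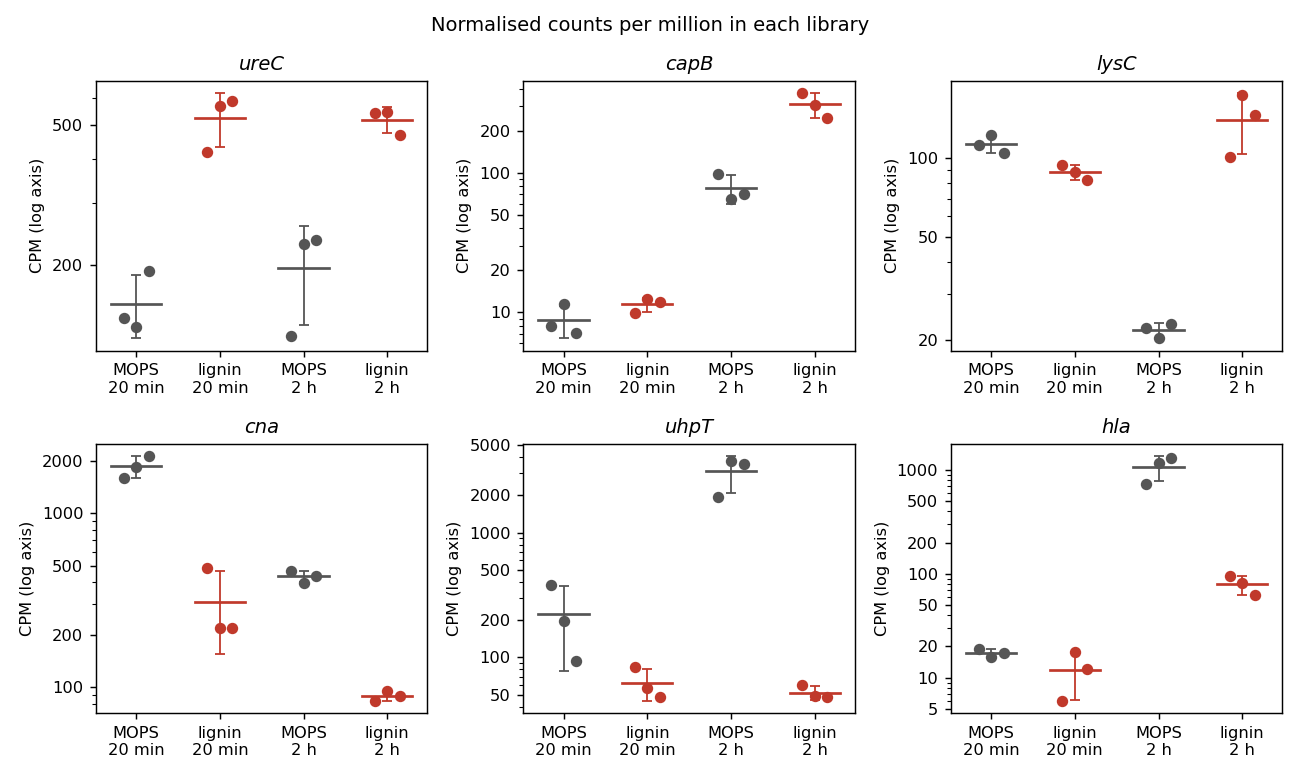
Normalised counts (CPM, log axis) of 6 genes in each library; points are libraries, horizontal bars are means and whiskers are SD over 3 libraries. ureC was higher with lignin at both times and cna lower at both, while hla differed by a log2 fold change of -3.75 at 2 h.

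After 2 h of lignin, 16 of 16 capsule, 6 of 6 lysine, 8 of 9 tryptophan and 7 of 7 urease list genes were higher than in MOPS. Lower were 6 of 6 measured genes of the fermentation list and 6 of 9 of the nitrate respiration list, nrdD and nrdG among them. Also lower were 13 of 15 of the glycolysis and pyruvate dehydrogenase list and 5 of 8 of the agr and toxin list. As lists, none of these held in camera with an estimated correlation (adjusted p from 0.242 to 0.677). uhpT, for hexose phosphate uptake (246978 to 248357), stood at 52.3 ± 6.65 CPM with lignin and 3087 ± 1017 in MOPS, a 59.0-fold difference. hla, encoding alpha-toxin (1180442 to 1181401), stood at 79.5 ± 16.3 against 1072 ± 292 CPM. capD of the capsule operon reached 683 ± 232 against 158 ± 8.56 CPM. In all, 1041 of 2589 features changed, 512 higher and 529 lower (edgeR adjusted p under 0.05). Of these, 346 carried a symbol, 642 a locus tag only, and 53 were SARs features.

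Under naming rule (a), the other large falls at 2 h were in purA, for adenylosuccinate synthetase, at -5.76 (SE 0.79), the surface protein gene sasD at -4.83 (SE 0.23), and lrgA and lrgB, of an antiholin-like operon, at -4.72 (SE 0.60) and -3.73 (SE 0.38). pyrAA, for a carbamoyl phosphate synthase subunit, followed at -3.48 (SE 0.88) and lldP2, for lactate uptake, at -3.33 (SE 0.29). The largest rises under that rule, which leaves out genes under 10 CPM, were in fadX at 2.84 (SE 0.31), pbuX, for xanthine uptake, at 2.70 (SE 0.40), the riboflavin genes ribE and ribD at 2.69 (SE 0.21) and 2.54 (SE 0.17), and lysC, for aspartokinase, at 2.69 (SE 0.23). cap8I rose by 2.48 (SE 0.43), xpt, next to pbuX, by 2.47 (SE 0.40), and rir1, of ribonucleotide reductase, by 2.32 (SE 0.21). The edgeR adjusted p of these 16 genes, uhpT and hla included, lay between 0.000101 (sasD) and 0.0215 (pyrAA). All reads of fadX also fall in an overlapping SARs feature of the annotation, so its value is uncertain. The pyrAA call was lost in edgeR without MOPS 2 h replicate 2 or 3, or without any of lignin replicates 1, 2 and 3.

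Of the 39 lists tested at 2 h, camera with the preset correlation called 7 up and 5 down, with adjusted p from 6.25e-08 (capsule) to 0.0426 (osmotic, pH and ion). With an estimated correlation none held: adjusted p = 0.242 for tryptophan and fermentation, adjusted p = 0.266 for lysine, adjusted p = 0.496 for branched-chain amino acids and adjusted p = 0.677 for the other 8. Of the 10 splits of the 6 libraries, 2 gave at least 12 lists, the real one included. Capsule rose in 16 of 16 genes, lysine synthesis in 6 of 6, tryptophan synthesis in 8 of 9, branched-chain amino acids and threonine in 8 of 11 and urease in 7 of 7. The sigma B list had 6 risen and 1 fallen of 11, and the osmotic, pH and ion list 10 risen and 2 fallen of 21. Fermentation fell in 6 of 6, nitrate respiration in 6 of 9, glycolysis with pyruvate dehydrogenase in 13 of 15, the agr and toxin list in 5 of 8 and heat shock in 5 of 12. Those fallen in the agr and toxin list were agrA, agrB, agrC, agrD and hla. Its other toxin genes hlgA, hlgB and hlgC, at -0.48, 0.01 and 0.34, did not pass. Adjusted over the list alone, the counts were 8 fallen for nitrate respiration, 9 risen for branched-chain amino acids, 7 risen for sigma B and 11 risen for the osmotic list, and were otherwise as given.

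In the capsule operon, capB rose by 1.99 (SE 0.23) and capD by 2.11 (SE 0.25), with edgeR adjusted p = 0.000936 and adjusted p = 0.00105. asd and dapB of the lysine pathway rose by 1.98 and 1.52, trpB and trpC by 1.94 and 1.97, and thrB and leuC by 1.59 and 1.15. ureC stood at 519 ± 42.9 against 197 ± 61.8 CPM and ureF at 149 ± 21.2 against 65.9 ± 9.09 CPM. Among sigma B genes, opuD2, for glycine betaine uptake, rose by 1.48 and the anti-sigma factor gene rsbW by 1.59. The other members that rose were sigB, rsbV, crtM and crtN. The member that fell was clpL, at -1.78, named after its value was seen. asp23, spoVG, yabJ and rsbU, at 0.073, 0.105, 0.531 and 0.337, did not pass. mnhA, for sodium and proton exchange, rose by 0.79 and kdpB by 0.78. Of the other direction, adhA, for alcohol dehydrogenase, fell by 3.26, the lactate dehydrogenase genes ldh2 and ddh by 1.79 and 1.72, and adhE by 1.82 on the log2 scale. nrdD, for anaerobic ribonucleotide reductase, fell by 2.38 and nasE, for nitrite reductase, had a log2 fold change of -2.30. The pyruvate dehydrogenase genes pdhA and pdhD fell by 1.34 and 1.31 and gapR by 1.03 on the log2 scale. The chaperone genes groES and groEL fell by 2.22 and 1.45 on the log2 scale.

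Of the regulators, agrA fell to 4043 ± 212 from 8339 ± 1418 CPM (edgeR adjusted p = 0.00243), and agrB, of the same operon, fell to 3768 ± 873 from 7528 ± 922 CPM, calls that limma on the authors' normalized RPKM did not make. sigB rose to 1014 ± 166 from 513 ± 60.7 CPM (edgeR adjusted p = 0.0044). SARs022, a feature of the agr locus that spans hld and was named after its value was seen, stood at 1636 ± 345 against 2462 ± 171 CPM (log2 fold change -0.59, edgeR adjusted p = 0.036), a call lost in edgeR without MOPS 2 h replicate 2 or 3 or without lignin replicate 2 or 3, and lost with total counts. saeR and saeS had values of -1.09 and -1.27 with edgeR adjusted p = 0.0879 and adjusted p = 0.115, and both passed without MOPS replicate 2 or with DESeq2. vraS stood at -0.05, yycG at -0.13, yycF at -0.34 and sarA at 0.23, none of which passed; yycF passed without MOPS replicate 1. MOPS 2 h replicate 1 stood apart, with correlations of 0.954 and 0.957 to replicates 2 and 3, which correlated with each other at 0.990. Without it 1321 features changed (688 higher, 633 lower), and the pyrimidine, TCA cycle and cid and lrg lists were called, down, at camera adjusted p = 1.56e-09, adjusted p = 0.0281 and adjusted p = 0.0045, each with adjusted p = 0.502 with an estimated correlation. Leaving out lignin 2 h replicate 2 lowered the number of changed features to 658. With total counts in place of TMM the median gene moved by 0.39 on the log2 scale and the calls split into 965 higher and 309 lower. No median of a list called at 2 h changed sign with that scaling. The agr list was not called without MOPS replicate 1 or lignin replicate 1, sigma B without MOPS replicate 2 or 3, heat shock without MOPS replicate 2 or 3 or lignin replicate 1 or 3, and the osmotic list without MOPS replicate 2 or 3 or lignin replicate 1.

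The same-direction overlap of the calls at both times was 93 features for higher and 69 for lower among 2577 tested at both. Independent lists of these sizes would share 46.7 and 55.5 (one-sided Fisher exact test over genes, which are not independent replicates, p = 1.69e-13 and p = 0.0212). The comparisons share no library. A further 17 features were higher at 20 min and lower at 2 h, and 40 were lower at 20 min and higher at 2 h. Without lignin 20 min replicate 1, the overlaps were 140 and 148, against 100.22 and 106.21 for independent lists, an alternative added after seeing the data.

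The lignin response itself differed between the times for 741 of 2632 features, of which 347 had the higher log2 effect at 2 h and 394 the lower (edgeR adjusted p under 0.05). Under naming rule (a), which leaves out genes under 10 CPM such as ilvH (3.18), the largest shifts upward were in gltD of glutamate synthesis at 3.18 (SE 0.46), ilvC at 3.16 (SE 0.67), lysC at 3.01 (SE 0.28), fadX at 2.98 (SE 0.44) and putP, for proline uptake, at 2.98 (SE 0.32). The largest downward under it were in purA at -6.50 (SE 0.93), lrgA at -4.73 (SE 0.69), the phenol-soluble modulin feature PSMa at -4.41 (SE 0.51), uhpT at -4.10 (SE 0.63) and the staphylokinase gene sak at -3.88 (SE 0.79). Their edgeR adjusted p lay between 0.000144 (lysC) and 0.00699 (ilvC). sak lies at one end of the sak to int stretch, and its log2 change at 20 min was -0.016, 3.023 and 2.917 in lignin replicates 1, 2 and 3. It was not called at 20 min (edgeR adjusted p = 0.0613). Of this stretch, 47 features were among the 741, and its rise at 20 min was absent from lignin replicate 1. The count of 741 became 478 without MOPS 20 min replicate 2, 476 without MOPS 2 h replicate 3, and 429 and 431 without lignin 2 h replicates 2 and 3. With total counts the split was 630 higher and 219 lower, for a shift of the median gene of 0.39, and on the authors' normalized RPKM limma gave 436 higher and 289 lower.

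In MOPS alone, 1285 of 2591 features changed from 20 min to 2 h, 645 of them higher and 640 lower (edgeR adjusted p under 0.05). PSMa rose from 2.54 ± 0.229 to 570 ± 219 CPM, the lipase gene geh from 32.2 ± 7.40 to 3616 ± 392.4, hla from 13.7 ± 1.13 to 1162 ± 291, adhA from 152 ± 108 to 6212 ± 2420 and the purine gene purD from 355 ± 34.8 to 13810 ± 1944. The glucose uptake gene glcU fell from 575 ± 154 to 65.0 ± 27.99 CPM. The log2 fold changes of trpF, trpC and gatC were -2.74, -2.48 and -2.64. arcC fell from 19.9 ± 14.8 to 0.577 ± 0.999 CPM, but all of its reads also fall in an overlapping SARs feature. With total counts the median gene moved by -0.64 and the calls split into 353 higher and 1259 lower, and on the authors' normalized RPKM limma gave 391 higher and 1149 lower.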

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

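The tests on the sak to int stretch and on lignin 20 min replicate 1 were chosen after the results were seen, and those on DNA copies and on a mixture were rewritten after a first version had been run; the splits of the libraries and, except where stated, the tests on the course of MOPS were set beforehand. Of 91 named genes tested, 53 were singled out because the lignin effect differed between 2 h and 20 min (edgeR interaction test, adjusted p under 0.05). Values are the log2 effect at 2 h minus that at 20 min. Besides the 10 genes named for this comparison in the results (purA -6.50, lrgA -4.73, PSMa -4.41, uhpT -4.10, sak -3.88, putP 2.98, fadX 2.98, lysC 3.01, ilvC 3.16 and gltD 3.18), the effect was lower at 2 h for clpL (-3.63), nrdD (-3.61), lrgB (-3.47), sasD (-3.38), hla (-3.23), adhA (-3.06), bbp (-2.98), sdrC (-2.78), adhE (-2.29), SARs022 (-2.25), acpD (-2.17), sasF (-1.94), kdpA (-1.73), sstA (-1.63), pyrG (-1.58), gapR (-1.44), ldh2 (-1.40), pdhD (-1.35) and pdhA (-1.20). It was higher at 2 h for sigB (0.91), thrB (1.08), citZ (1.48), rir1 (1.53), rocD (1.55), capB (1.58), mnhA (1.62), scrA (1.63), cap8I (1.63), opuD2 (1.65), rsbW (1.66), scrR (1.73), rocF (1.76), capD (1.80), leuC (2.19), malA (2.38), mprF (2.58), gntP (2.59), dapB (2.63), dapA (2.69), dapD (2.69), asd (2.71), leuA (2.93) and ilvH (3.18).

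The 20 min, 2 h and MOPS time comparisons allow 10 splits of 6 libraries each, too few for a share under 0.05. The real splits gave 510, 1041 and 1285 features, each the only 1 of the 10 with so many, and the highest of the others was 0 in each. For the lists the real splits gave 8 at 20 min and 12 at 2 h. Of the 10 splits, 10 gave at least as many at 20 min and 2 at 2 h, with highest others of 19 and 14. For the difference between times, 2 of 100 splits drawn gave at least the real 741, a share under 0.05. These splits mix lignin and MOPS within each time, so the low share bears only on the case of no lignin effect at either time. Equal effects at both times were not tested by them. Since the replicates may be technical, neither was a difference between cultures apart from lignin. The other split with at least 741, at 1024, exchanged lignin and MOPS for all 6 libraries of 2 h, and the next gave 576.

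At 20 min the stretch from sak to int (2128315 to 2168433 on the MRSA252 reference, 68 features, 56 tested) was higher in lignin replicates 2 and 3 and not in replicate 1; without replicate 1, 51 of the 56 passed as higher and 1 as lower, and at 2 h the median lignin effect was 0.31. Too few reads in replicate 1 were argued against by its 17001363 gene reads, the most of the 12 libraries. For extra copies of the DNA in the libraries the test did not decide: 10.71% of the features (6 of 56) gained less than 10% of the median gain of 780.7 CPM per kb. The exact 95% interval of that share, 4.03 to 21.88%, spans the bounds set for it, and it takes neighbouring features as independent. Gains ran from -248.1 to 2169.2 CPM per kb. The neighbours SAR2100 to SAR2104 changed by -0.23 to 0.78 on the log2 scale in replicates 2 and 3, beside 6.52 and 6.41 for SAR2099. These values argue against even copies of the whole stretch as the sole cause, while copies of a part of it were not tested. The 7 measured genes of the SOS list had a median log2 change of 0.065 in replicates 2 and 3, with recA at -0.33, which argues against a raised SOS response at this time. An effect of lignin on a prophage-like element, or a difference between these cultures apart from lignin, may account for the rise, and neither was tested.

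Lignin 20 min replicate 1 also stood apart from the other lignin libraries of 20 min over genes. Its correlations with the MOPS 20 min libraries (0.940 to 0.949) were higher than with lignin replicates 2 and 3 (0.905 and 0.914). Those with the lignin 2 h libraries were about as high, at 0.9324, 0.9465 and 0.9434, and those with the MOPS 2 h libraries lay between 0.9015 and 0.9141. Why it was near the 2 h lignin libraries was not tested. A swap with a MOPS library would need a MOPS 20 min library nearer to lignin replicates 2 and 3 than to the other MOPS libraries, but the largest such difference in correlation was -0.0679. A single mixture of both kinds of RNA would bring every gene the same share of the way from MOPS to replicates 2 and 3. That share was a median of -0.001 for 48 features of the stretch, 0.134 for 67 other genes at least 4-fold higher and 0.734 for 70 at least 4-fold lower. Lower minus stretch was 0.735, with the quartiles apart, which argues against a single mixture that takes in the stretch. The stretch had been singled out because its rise was absent from replicate 1. A first version that set the stretch against the higher genes did not decide. For the other higher and lower genes the quartiles overlapped, at 0.007 to 0.445 and 0.27 to 0.948. A mixture that leaves the stretch aside was therefore not decided. A weaker or later exposure of this culture may account for part of the pattern and was not tested.

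Lignin effects at 2 h covaried negatively over genes with the changes with time in MOPS, at -0.641. In 100 simulations of unchanged groups the covariance lay between -0.148 and -0.082. This argues against spread of the size seen between replicates, in the shared MOPS 2 h libraries, as the whole cause, although part may come from it. The replicates may be technical, so a larger deviation common to the MOPS 2 h libraries was not covered by the simulations. The share of changed features that moved opposite to the change with time was 74.7% (778 of 1041), and the correlation was -0.50. The simulations gave 74.35 to 80.50% of as many features with the largest changes, and -0.51 on average. The simulated groups held no real change, so the sharing alone sets their share and correlation, whatever the spread. These measures therefore cannot tell the sharing from a real opposition of the effects. The share was added after the results were seen. For slower progress along the MOPS course, lignin means were set against the range between both MOPS means. No library was taken between the 2 sampling times, so a gene that peaked or dipped there could lie outside through a delay alone. Slower progress as the whole cause is therefore argued against only if levels in MOPS stayed within that range. Whether they did was not measured, so the test did not decide. Of the changed features, 49.28% (513) had a lignin mean outside the range by more than 2 SE. Of these, 263 moved in the same direction as the change with time, where a call all but ensures a place outside, and 250 moved opposite to it. The 16 of 16 capsule and 7 of 7 urease calls that lay outside were all of the former kind. Only 2 of 13 glycolysis calls and 0 of 6 fermentation, 0 of 6 nitrate respiration, 0 of 6 TCA cycle, 0 of 5 agr and toxin and 0 of 4 aerobic respiration calls lay outside. A delay may account for part of the fall in the latter lists, as an open hypothesis.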

How the results depend on the processing

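Unique gene reads, limma on the authors' normalized RPKM, the removal of SARs features and the overlap without a library were chosen after seeing the data. At 20 min the number of changed features went from 510 to 795 with DESeq2, to 816 with all 12 libraries in one fit and to 19 at an adjusted p under 0.01; leaving out single libraries gave 1 to 1050. At 2 h the 1041 became 578 with an absolute log2 fold change of at least 1 and 589 under 0.01, and 658 to 1321 with a library left out. The difference between times went from 741 to 256 under 0.01 and to 429 to 1028 with a library left out, and time in MOPS from 1285 to 855 with the fold limit and 736 under 0.01. A stricter threshold lowers a count by construction; the cause of the other shifts was not tested. The overlap of both times was 162 features, 249 with DESeq2, 74 with the fold limit and 288 without lignin 20 min replicate 1. Lists called went from 8 and 12 to 0 and 0 with an estimated correlation (2 and 3 at an unadjusted p under 0.05), to 22 with fry at 2 h, and to 6 to 13 at 20 min with a library left out. At 20 min fry called 9 lists, but only 4 of the 8. It did not call capsule (fry adjusted p = 0.0522), or ATP synthase, D-alanylation and lysine (fry adjusted p = 0.0711 each). The other alternative counts, the replicate block apart, lay within 1.5 times of the main ones.

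Whether replicate numbers pair the libraries stayed open at 20 min, and at 2 h the deviations from the group means gave no sign of it. Deviations of same-numbered lignin and MOPS libraries correlated at 0.202, 0.087 and 0.210 at 20 min and at -0.228, -0.231 and -0.030 at 2 h. At 20 min each MOPS library correlated best with the lignin library of its own number. Lignin 20 min replicate 2, however, did so with MOPS replicate 3, at 0.093 against 0.087. Replicates 2 and 3 were nonetheless the closest pair over genes in lignin 20 min, MOPS 2 h and lignin 2 h. In lignin 2 h replicate 1 correlated with them at 0.9754 and 0.9761, against 0.9899 between them. In MOPS 20 min replicates 1 and 2 were the closest, at 0.9839. The labels name no batch. Whether replicate 1 was handled apart, or replicates 2 and 3 were independent, was not tested. With the replicate block the counts were 409, 751, 642 and 1138, the overlap 100, and the lists 8 and 10. With the block, camera did not call the tryptophan list at 20 min (adjusted p = 0.0609) or the sigma B and osmotic lists at 2 h (adjusted p = 0.0684 and adjusted p = 0.0584). Of 35 named calls at 20 min, 29 held under every other setting with all libraries kept, 11 were not called with the block, and 0 held under every removal of a library. Of 52 at 2 h it was 45, 2 and 50. No named gene reversed. The pseudocounts planned for tables without counts were not needed. Of simulated 2-fold changes, 6.0% were called for the difference between times and 13.4% at 20 min, where the libraries were not the shallowest but the common biological coefficient of variation was 0.365, against 0.259 at 2 h.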

Other observations

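Several gene groups outside the called lists held changed members. Of 12 surface adhesin genes, 5 rose and 1 fell at 20 min (camera adjusted p = 0.0579), with sdrC, bbp and sasF among the risen and cna the fallen; bbp went from 1.76 ± 0.594 to 13.8 ± 0.398 CPM. At 2 h 4 rose and 3 fell, with cna at -2.28 and sasD at -4.83. Of 10 arginine genes, 5 fell and 1 rose at 20 min (camera adjusted p = 0.0858), with rocF, for arginase, at -1.81 and rocD at -1.61 among those that fell. At 2 h 8 of 12 pyrimidine genes fell and 1 rose (camera adjusted p = 0.0535), with pyrG, for CTP synthase, at -1.64. Of 17 purine genes 5 rose and 3 fell at 2 h, while adjusted over the list alone 5 rose and 10 fell and the median was -1.73 (camera adjusted p = 0.388). Without MOPS 2 h replicate 1, counts added after seeing the data, 9 of 12 pyrimidine genes fell and 1 rose with a median of -2.90 (camera adjusted p = 1.56e-09, and adjusted p = 0.502 with an estimated correlation), while 5 of 17 purine genes rose and 2 fell with a median of -1.39 (camera adjusted p = 0.79, and adjusted p = 0.967 with an estimated correlation). Those that moved included the salvage genes pbuX and xpt and the GMP branch gene guaB (1.58) on one side and purA of the AMP branch on the other. fhuD and fhuB stood at 1.69 and 1.57 at 2 h, where 5 of 16 iron genes rose and 1 fell. mprF, which modifies membrane lipids with lysine, rose by 1.92 at 2 h. Of the 52 ribosomal protein genes 8 fell at 2 h and 0 changed at 20 min with edgeR. At 2 h their median was -0.03 (camera adjusted p = 0.768), and adjusted over the list alone 0 fell. Without MOPS 2 h replicate 1, 19 of them rose and 7 fell, with a median of 0.25.

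The patterns in this paragraph were looked for after the values were seen. A pair of runs of at least 20 neighbouring features held under 1 CPM in every library. The run from 33840 to 86980, which contains mecA, had 61 features with 1 read in all 12 libraries together, and the run from 1591992 to 1637413 had 67 features, also with 1 read. The protein A gene spa stood at 20419 CPM in lignin 20 min replicate 1 and at 3274 and 4258 in replicates 2 and 3. Of the features called here, 508 of 508 at 20 min and 1036 of 1041 at 2 h had the same direction in the authors' deposited table.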
